A study of Arabidopsis thaliana with 24 samples.

How the data were processed

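Whole Arabidopsis thaliana seedlings of the Columbia background were profiled by sequencing of polyA RNA. Per the labels' protocols, stratified seeds received 3 h of white light at 22 °C, germinated and grew for 3 days in darkness at 22 °C, and were then moved to 37 °C or kept at 22 °C for 3 h. The series describes its samples as biological triplicates, and the labels do not say whether the triplicates came from separate sowings or days, so p-values measure the spread between these libraries. The labels give 24 libraries of 4 genotypes or lines (WT, the pif4 mutant, and the lines PIF4-L.1 and PIF4-L.2) at both temperatures. Samples were grouped by the genotype and treatment in their titles, and the columns of the deposited table were tied to these groups by the column names.

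The deposited table holds raw read counts per gene, per the file headers and as whole numbers with a different total in each library show, together with length-corrected values. The latter enter none of the results given here, although an analysis of them was run and seen before it was left out. Per the submitters' processing notes the genome build was TAIR10. The aligner, the counting tool, the annotation and whether counting used strand are not given in the sources used here, so how reads of overlapping, antisense or nearly identical genes were split is unknown. The table lists 33602 genes, of which 1274 have no value in any column and 32328 were used. Of the identifiers, 32835 matched a locus of the reference annotation (TAIR10.1), which was used only for symbols, product names and gene neighbours, and no coordinates are printed because the builds differ.

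The columns of WT and pif4 name the genotype and a letter a, b or c. No label ties the letters to the replicate numbers, so a library is named here by group and letter. In all, 36 per-sample columns enter none of the results given here. Of these, 12 hold the length-corrected values of the libraries used. They were set aside after an analysis of them had been seen, because the names tie a column to a group and not to a labelled sample, so 1 measure per library was kept. The other 24, of 12 libraries, carry line codes that no label ties to PIF4-L.1 or PIF4-L.2, and those libraries were not analysed here. For that reason 10 of the 15 comparisons fixed before the data were examined were not run, and the fit holds 12 libraries in 4 groups of 3 in place of 24 libraries in 8 groups.

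Counts as deposited were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr by group, TMM scaling, robust quasi-likelihood fit and F test for changes in either direction). All 12 libraries entered the fit with no covariate. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 18774 genes kept. Fold changes are log2 with a standard error taken as the fold change divided by the square root of F. Levels are CPM, counts scaled to a common total by the TMM-scaled library size, as mean ± SD over 3 libraries. The biological coefficient of variation was 23.4%. A group with 0 reads over its 3 libraries was set to a floor of 3 reads over the group and the fold is then written as a bound, and with 1 to 3 reads the ratio is given with a 95% counting interval. These bounds and intervals cover counting error only. Zero counts were more frequent than counting error gives. Of genes for which the other libraries of the group predicted 5 to 10 reads in a library, 2.27 to 27.0% had 0 reads there, against 0.143 to 0.253% under a Poisson distribution. WT at 37 °C library c had the highest share.

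Detection was gauged on simulated negative binomial counts at the real library sizes, with no separate term for the extra zeros. Gene means were pooled over all 12 libraries, or over the compared groups for pif4 against WT, so the heat response was absent. The 200 genes changed by known amounts all had a mean of at least 5 CPM, so the recovery does not hold for genes with fewer reads. The 2-fold changes were recovered for 47.1% of genes in the comparison of heat in WT, 54.1% for heat in pif4, 53.1% for pif4 against WT at 22 °C, 55.8% at 37 °C and 14.1% for the difference between the heat effects. The 4-fold changes were recovered for 93.7, 93.1, 96.2, 89.4 and 80.7% of genes, and the 1.5-fold changes for 8.70, 10.4, 6.90, 5.26 and 3.08%. False calls made up 11 of 108, 10 of 117, 4 of 117, 2 of 107 and 2 of 61 calls, so for the 2 heat comparisons their share lay above the nominal 5%.

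Before the data were examined, 18 gene lists with 267 members were fixed. They cover small heat shock proteins, chaperones, heat shock factors, the unfolded protein response of the endoplasmic reticulum (ER), oxidative stress and osmolytes, PIF and light signalling, auxin, brassinosteroid with gibberellin and elongation, photosynthesis, chlorophyll synthesis, abscisic acid, ethylene with senescence, the circadian clock, the cell cycle, seed storage, light exposure, root, and reference genes. Of the members, 266 had values and 13 were not tested, among them HSFB1 (no values), SESA1, BIP3 and YUC9 (too few reads). Lists were compared with all other genes by camera (limma 3.58.1, voom weights, preset correlation between genes of 0.01), and again with an estimated correlation, each Benjamini-Hochberg adjusted over the lists. A further 14 gene families were defined from product names after the table was opened and before their values were seen.

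Genes were named by a rule fixed before the data were examined. It takes PIF4 in every comparison. For heat in WT it takes the 8 largest rises and the 8 largest falls among called genes whose libraries did not overlap and whose mean was at least 5 CPM in the higher group, and for the pif4 comparisons up to 6 in each direction. It also takes up to 4 called members of each list, or up to 2 of the highest mean over all 12 libraries where none was called. The text names a subset: per list the largest rise and the largest fall among called members, with all lists for heat in WT and elsewhere lists past the preset camera threshold. This narrowing was set after the values were seen, without use of the alternatives. UBC12, LEA18, RAB18, BRU6, PMZ, AT1G03106, AT5G38050, AT2G32150, CRA1, CRU2, CRU3 and, at the second temperature, RH12, EM1 and HSP17.4A stand outside the rule where they are named and were chosen after their values were seen.

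Each comparison was also computed with DESeq2 1.42.0, RLE size factors, no filter on low counts, total counts as library size (for heat in pif4 this was chosen after seeing the data), a fit of the compared groups alone, a 2-fold minimum, and leaving out each library in turn. Chosen after seeing the data were the column letter as a term of the model and a fit without the 4 libraries lettered a, which were the shallowest of their groups and held 3.43 to 8.34% of reads in AT2G01021, against 1.87 to 3.28% in the libraries lettered b and c. The pairs of libraries within a group differed by more than counting error (chi-square per degree of freedom 6.45 to 25.1), so none was treated as a copy of another.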

Results

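The data comprise 12 RNA-seq libraries of dark-grown Arabidopsis seedlings, 3 each of WT and of the pif4 mutant at 22 °C and after 3 h at 37 °C. PIF4 is a basic helix-loop-helix transcription factor of light and temperature signalling, and the series asks how seedlings grown in darkness respond to heat with and without it. Library totals were 3234886 to 14791597 reads in WT and 3176106 to 11099980 in pif4 at 22 °C, and 3360759 to 8263355 in WT and 5940624 to 10662414 in pif4 at 37 °C. The first principal component, with 69.2% of the variance, separated the temperatures, and the second held 6.31%. On the second, all WT libraries had positive values (2.04 to 79.8) and all libraries labelled pif4 negative ones (-67.4 to -3.76). Library c at 37 °C was the extreme of each genotype. This separation was not tested.

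PIF4 (AT2G43010) itself was read in every group. WT held 9.98 ± 2.90 CPM at 22 °C and 28.8 ± 5.91 CPM at 37 °C, a rise of 1.51 ± 0.28 (log2 ± SE, n = 3 against 3, adjusted p = 0.000147). The libraries labelled pif4 held 17.5 ± 6.42 CPM at 22 °C and 22.1 ± 0.532 CPM at 37 °C, a difference of 0.35 ± 0.27 that was not called (adjusted p = 0.299). Against WT, the PIF4 values of the libraries labelled pif4 differed by 0.76 ± 0.28 at 22 °C (adjusted p = 0.809) and by -0.40 ± 0.27 at 37 °C (adjusted p = 0.681). Leaving out 1 library moved these values between 0.44 (without pif4 b) and 1.04 (without WT b) at 22 °C and between -0.54 and -0.28 at 37 °C. It moved the heat difference in pif4 between 0.0875 (without pif4 c at 22 °C) and 0.675 (without pif4 b at 22 °C), none of them called. PIF4 counts were therefore not lower in the libraries labelled pif4 at 22 °C, and counts per gene hold no position along the transcript, so they do not check these labels. The rise in WT depended on the scaling: with total counts as library size it was 0.49 (adjusted p = 0.133). In the libraries labelled pif4 the direction turned, to -0.68 (adjusted p = 0.0425).

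Heat moved the WT transcriptome toward the heat shock proteins. The 15 genes of the small heat shock protein list, chaperones that bind unfolding proteins, took 0.006 to 0.008% of all reads at 22 °C and 11.6 to 13.4% at 37 °C over both genotypes. HSP18.2 (AT5G59720) went from 1.11 ± 0.0966 to 43273 ± 5052 CPM, a log2 change of 15.24 ± 0.29, and mitochondrial HSP23.6-MITO (AT4G25200) from 0.325 ± 0.158 to 12023 ± 1516 CPM (15.30 ± 0.28). APX2 (AT3G09640), a cytosolic ascorbate peroxidase, had 1 read in WT at 22 °C and 2454 ± 315 CPM at 37 °C, a ratio with a counting interval of 20747 to 4566200. Among the falls, ENODL15 (AT4G31840), an early nodulin-like protein, dropped from 11.6 ± 1.104 CPM to 0 reads, at least 51.0-fold lower. In all, 9672 of 18774 genes were called, 4793 higher and 4879 lower, and 6968 of them changed at least 2-fold (3167 higher and 3801 lower).

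The counts of higher and lower genes are relative to the scaling. TMM factors were 1.301 to 1.497 at 22 °C and 0.68 to 0.73 at 37 °C, and the median of all genes lay at -0.12. With total counts as library size it lay at -1.13, a shift of -1.02, and 13425 genes were called with 13.3% of them higher, against 49.6% higher under TMM.

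Besides HSP18.2, HSP23.6-MITO and APX2, the 8 largest rises were the plastid HSP21 (15.16 ± 0.27), HSP17.6C-CI (14.77 ± 0.34), HSP17.6II (14.69 ± 0.37), HSP26.5 and HSP17.4A (14.21 ± 0.30). HSP26.5 had 2 reads at 22 °C, so its ratio has a counting interval of 7456 to 222460. The 8 largest falls all ended at 0 reads at 37 °C. After ENODL15 they were AT5G49960 (at least 41.6-fold lower), MEE53 (39.3), UGT76E4, a glycosyltransferase (32.6), AT3G24210 (32.3), AT3G14740 (29.7), AT2G45750 (29.3) and the receptor-like kinase SD1-29 (27.9), each from 6.38 to 9.38 CPM at 22 °C. As zero counts were more frequent than counting error gives, up to 27.0% where 5 to 10 reads were predicted, these bounds are not limits on biological variation.

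Of the 15 small heat shock protein genes, 14 rose and HSP15.4 fell (-0.91 ± 0.27, adjusted p = 0.00809), with a list median of 13.19 (camera adjusted p = 5.53e-17, and 0.0222 with an estimated correlation). Without the 4 libraries lettered a, HSP15.4 lay at -0.75 (adjusted p = 0.0607). Of 20 other chaperones, 19 rose and none fell, with a median of 6.08 (adjusted p = 5.25e-27, and 0.000425 with an estimated correlation). The cytosolic HSP70B (AT1G16030) rose from 5.58 ± 0.674 to 20811 ± 3082 CPM (11.86 ± 0.29) and the peptidyl-prolyl isomerase ROF2 from 7.65 ± 1.88 to 13633 ± 1312 CPM (10.85 ± 0.23). Among 21 heat shock transcription factors, 16 rose and 1 fell, with a median of 3.15 (adjusted p = 1.13e-08, and 0.00324 with an estimated correlation). HSFA2 (AT2G26150) rose from 1.39 ± 0.748 to 2064 ± 265 CPM (10.49 ± 0.32), and HSFA5 fell from 15.2 ± 1.47 to 7.37 ± 0.506 CPM (-1.06 ± 0.27).

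The unfolded protein response of the ER rose as well, in 11 of 13 genes with none lower (median 2.32, adjusted p = 2.28e-09, and 0.0161 with an estimated correlation). Its J-domain co-chaperone ERDJ3A rose by 7.51 ± 0.27 to 584 ± 45.3 CPM, and the lumenal HSP70 BIP1 by 3.76 ± 0.15 to 407 ± 49.9 CPM. Of 13 oxidative stress and osmolyte genes 10 rose (median 2.03, adjusted p = 8.94e-07, and 0.0375 with an estimated correlation). Next to APX2 stood GOLS1, a galactinol synthase that starts raffinose synthesis, at 6.48 ± 1.47 CPM before and 5150 ± 484 CPM after heat (9.70 ± 0.23). In the clock list 7 of 11 genes rose and 1 fell (median 1.74, adjusted p = 0.00478, and 0.0497 with an estimated correlation). PRR9 rose by 5.35 ± 0.47 to 24.8 ± 9.07 CPM, and LHY, a morning-phased MYB factor, fell by 1.88 ± 0.26 on the log2 scale to 13.1 ± 4.37 CPM. Abscisic acid response genes rose in 9 of 12 cases and fell in 1 (median 1.27, adjusted p = 0.00108, and 0.0645 with an estimated correlation), with RD29A at 3.33 ± 0.23 and the seed transcription factor ABI5 at -1.98 ± 0.54. Fewer members of these lists were called higher under total counts as library size. There the called members, higher and lower, were 12 and 2 for heat shock factors (median 2.12) and 9 and 2 for the ER list (1.302). They were 8 and 4 for oxidative stress (1.01), 6 and 4 for the clock (0.72) and 5 and 2 for abscisic acid (0.26).

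Genes of greening gave smaller changes whose direction was relative to the scaling. Of 24 photosynthesis genes 17 were called higher and 3 lower (median 0.92, adjusted p = 2.01e-05, and 0.324 with an estimated correlation). The light-harvesting genes went both ways: LHCB1.5 rose from 120 ± 10.6 to 1233 ± 124 CPM (3.37 ± 0.23) and LHCB2.3 fell from 54.0 ± 4.85 to 2.82 ± 2.41 CPM (-4.30 ± 0.51). Of 14 chlorophyll synthesis genes 7 were higher and 2 lower (median 0.60, adjusted p = 0.0265, and 0.263 with an estimated correlation), with the cyclase CRD1 at 2.38 ± 0.19 and the greening regulator GLK1 at -1.52 ± 0.38. In the PIF and light signalling list 10 of 19 were higher and 2 lower (median 0.48, adjusted p = 0.0318, and 0.0783 with an estimated correlation). There PIF7 had 2 reads at 22 °C and 6.27 ± 0.625 CPM at 37 °C, a ratio with a counting interval of 38.0 to 1188, and PIF8 was lower (-2.96 ± 0.98). As each library was left out PIF8 lay between -8.67 and -2.28. Its call ended without WT library c at 22 °C (adjusted p = 0.0563), without library b at 37 °C (0.065) and under DESeq2 (0.107). Ethylene and senescence genes were higher in 6 of 11 cases and lower in none (median 0.71, adjusted p = 0.0318, and 0.213 with an estimated correlation), led by BI1, a suppressor of cell death (3.12 ± 0.15), and the ethylene receptor ETR2 (1.44 ± 0.18). With total counts as library size the medians of these 4 lists turned to -0.10, -0.41, -0.53 and -0.29.

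**Figure D1:**
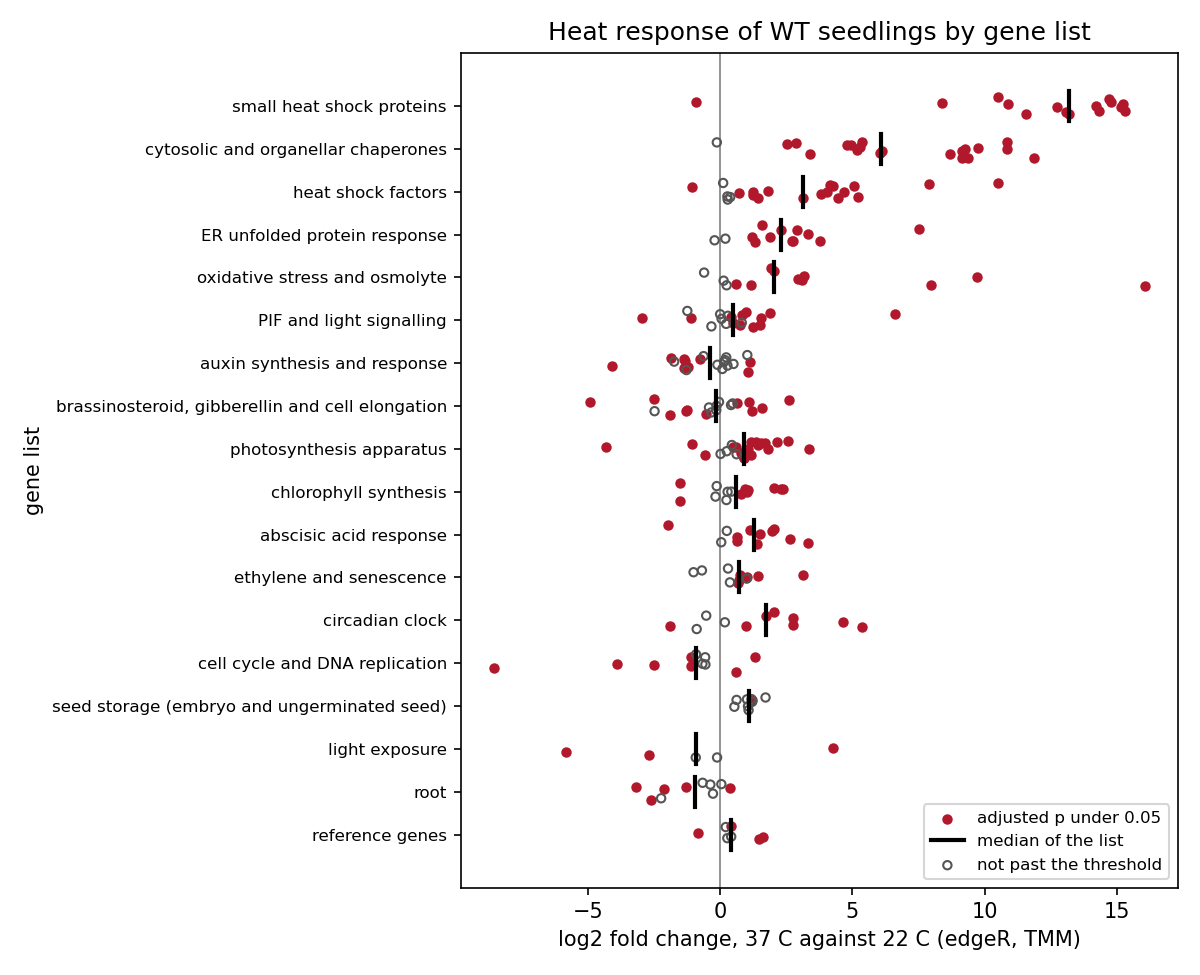
Each point is a gene of 1 of the 18 lists (vertical axis) at its log2 fold change in WT seedlings at 37 °C against 22 °C, 3 libraries each (horizontal axis). Filled points passed an adjusted p of 0.05 and black bars are list medians, from 13.19 for small heat shock proteins to -0.96 for root genes. The scale is TMM, and with total counts all genes shift by -1.02 at the median, which turns the medians of PIF and light signalling, photosynthesis, chlorophyll, ethylene and reference genes below 0.

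No growth-related list was past the threshold, and their counts depended on the scaling. Auxin genes were higher in 2 and lower in 7 of 20 cases (median -0.36, adjusted p = 0.382), from GH3.3, an auxin-conjugating enzyme (1.13 ± 0.21), to SAUR15, which had 80 reads at 22 °C and 1 read at 37 °C, a ratio with a counting interval of 4.14 to 949. The SAUR15 call ended without WT library c at 22 °C (adjusted p = 0.0864) or library b at 37 °C (0.0701). Brassinosteroid, gibberellin and elongation genes were higher in 5 and lower in 6 of 19 cases (median -0.14, adjusted p = 0.904). Here the gibberellin 3-oxidase GA3OX1 rose from 19.1 ± 2.68 to 117 ± 16.9 CPM (2.60 ± 0.18) and PRE1, a helix-loop-helix growth factor, fell from 13.4 ± 2.39 to 0.356 ± 0.474 CPM (-4.90 ± 0.56, or -6.60 to -4.43 as each library was left out). Cell cycle genes were higher in 2 and lower in 5 of 11 cases (median -0.91, adjusted p = 0.0974). The mitotic cyclin CYCB1;2 fell from 5.20 ± 1.29 CPM to 0 reads, at least 24.9-fold lower, while the replication clamp PCNA1 was higher (1.34 ± 0.27). With total counts as library size the counts of higher and lower genes became 0 and 14 for auxin (median -1.39), 2 and 14 for brassinosteroid, gibberellin and elongation (-1.17) and 0 and 9 for the cell cycle (-1.90), and GH3.3 lay at 0.11 (adjusted p = 0.669), PCNA1 at 0.32 (0.304) and ETR2 at 0.42 (0.0587).

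The lists for other tissues and for sample handling were not past the threshold either. Root genes were higher in 1 and lower in 4 of 10 cases (median -0.96, adjusted p = 0.0703). Under total counts it was 0 and 9 (median -1.998). CASP2, a Casparian strip protein of the root endodermis, fell from 57.4 ± 4.28 to 6.39 ± 0.556 CPM (-3.17 ± 0.22). The nitrate transporter NRT1.1 was called higher (0.37 ± 0.14, adjusted p = 0.0298) but turned to -0.65 with total counts, and its call ended without WT library a at 22 °C (adjusted p = 0.119), library c at 22 °C (0.0699), library a at 37 °C (0.0587) or library c at 37 °C (0.113). Seed storage genes were called in 1 of 9 cases, the oleosin OLEO2 (1.22 ± 0.32, but 0.21 with an adjusted p of 0.593 under total counts and 0.80 with an adjusted p of 0.0904 without the libraries lettered a), with a median of 1.08 (adjusted p = 0.382). Of 5 genes that report light exposure, ELIP1 rose (4.28 ± 0.37) and 2 fell (median -0.92, adjusted p = 0.935), or 1 and 4 with total counts (median -1.93). Among the latter, the flavonol synthase FLS1 had 38 reads at 22 °C and 0 at 37 °C, at least 3.76-fold lower, a call that ended without WT library b at 22 °C (adjusted p = 0.0524), library b at 37 °C (0.0555) or library c at 37 °C (0.0526). Of 7 reference genes 3 were higher and 1 lower (median 0.40, adjusted p = 0.0553). Under total counts it was 2 and 5 (median -0.61). UBQ10 rose from 570 ± 69.4 to 1760 ± 292 CPM (1.62 ± 0.15), and SAND was lower (-0.82 ± 0.33, adjusted p = 0.0456). The SAND call ended without WT library b or c at 22 °C (adjusted p = 0.119 and 0.144) or library a or c at 37 °C (0.15 and 0.173). Adjusted over the list alone, the counts of higher and lower members differed from those over all genes tested in 3 lists: 10 and 1 for oxidative stress, 10 and 3 for PIF and light signalling, and 7 and 7 for brassinosteroid, gibberellin and elongation.

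The libraries labelled pif4 gave a heat response of similar size. HSFA2 rose from 0.566 ± 0.370 to 2766 ± 200 CPM (12.62 ± 0.37), HSP21 by 16.01 ± 0.29, HSP70B by 11.86 ± 0.29 and ROF2 by 11.44 ± 0.24. Of 18774 genes, 9336 were called, 4810 higher and 4526 lower. Of the genes higher in WT, 4196 were also higher here (1228 for independent lists of these sizes), 3505 were lower in both (1176 for independent lists) and 1 went in opposite directions. Across genes, which are not independent replicates, the log2 fold changes of both genotypes correlated with r = 0.862 (Spearman 0.893), and with r = 0.956 over the 13586 genes with a mean of at least 5 CPM. With total counts as library size 13393 genes were called with 13.1% higher, against 51.5% under TMM.

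Small heat shock proteins were higher in 14 and lower in 1 of 15 cases (median 12.58, camera adjusted p = 8.58e-17, and 0.0240 with an estimated correlation), HSP15.4 again being the member that fell (-0.96 ± 0.27). Chaperones rose in 19 of 20 cases (median 6.35, 1.93e-26 and 0.000429 with an estimated correlation as adjusted p). Heat shock factors rose in 16 and fell in 1 of 21 cases (median 3.58, adjusted p = 1.76e-08, and 0.00439 with an estimated correlation), where HSFA1B, a factor of the heat shock response, lay at -1.37 ± 0.38. ER unfolded protein genes rose in 11 of 13 cases (median 2.24, adjusted p = 3.96e-09, and 0.0161 with an estimated correlation), with ERDJ3A at 8.12 ± 0.28 and BIP1 at 3.57 ± 0.15. Oxidative stress genes rose in 10 and fell in 1 of 13 cases (median 1.68, adjusted p = 1.42e-06, and 0.0346 with an estimated correlation). APX2 had 1 read at 22 °C and 2186 ± 206 CPM at 37 °C, a ratio with a counting interval of 11542 to 2540200, and the glutathione transferase GSTU1 was lower (-0.69 ± 0.25). Abscisic acid genes rose in 9 and fell in 1 of 12 cases (median 1.13, adjusted p = 0.000121, and 0.0346 with an estimated correlation), with RD29A from 11.9 ± 6.13 to 192 ± 3.72 CPM and ABI5 at -1.56 ± 0.52. Clock genes rose in 7 and fell in 2 of 11 cases (median 1.76, adjusted p = 0.00399, and 0.0347 with an estimated correlation), with PRR9 at 5.38 ± 0.49 and ELF4 at -3.45 ± 0.82. Called members, higher and lower, were 13 and 2 for heat shock factors under total counts (median 2.54). With the same scaling they were 9 and 2 for the ER list (1.21), 7 and 3 for oxidative stress (0.66), 5 and 2 for abscisic acid (0.0979) and 6 and 4 for the clock (0.73).

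Photosynthesis genes were higher in 15 and lower in 3 of 24 cases (median 0.68, adjusted p = 0.000260, and 0.408 with an estimated correlation), with LHCB1.5 at 2.89 ± 0.22 and LHCB2.3 at -3.88 ± 0.47. Chlorophyll synthesis genes were higher in 7 and lower in 3 of 14 cases (median 0.71, adjusted p = 0.0439, and 0.302 with an estimated correlation), with the protochlorophyllide reductase PORC at 2.31 ± 0.14 and GLK1 at -2.54 ± 0.39. Ethylene genes were higher in 6 and lower in 2 of 11 cases (median 0.74, adjusted p = 0.0250, and 0.180 with an estimated correlation), with BI1 at 3.27 ± 0.15 and the response factor ERF6 at -1.94 ± 0.68. With total counts the medians of these 3 lists turned to -0.32, -0.31 and -0.29. The other 8 lists were not past the threshold, with adjusted p from 0.0545 to 0.936, and for brassinosteroid, gibberellin and elongation the median (-0.07) was negative while the test pointed up. Adjusted over the list alone, the counts of higher and lower members differed for heat shock factors (17 and 1), oxidative stress (11 and 1), PIF and light signalling (8 and 3), brassinosteroid (7 and 6) and photosynthesis (16 and 3). The calls of GSTU1, ERF6 and ABI5 ended when a single library was left out: GSTU1 without libraries a or b at either temperature (adjusted p = 0.0665 to 0.115), ERF6 without a or b at 22 °C or b or c at 37 °C (0.0582 to 0.0988), and ABI5 without b at 22 °C (0.0699) or c at 37 °C (0.0673).

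At 22 °C, the oleosin OLEO5 (AT3G01570), an oil body protein, was higher in the libraries labelled pif4 than in WT, at 22.7 ± 3.81 against 6.69 ± 1.95 CPM (1.70 ± 0.28, adjusted p = 0.0182), and so was EM1 (AT3G51810), a late embryogenesis abundant protein, at 32.3 ± 4.70 against 10.5 ± 3.36 CPM (1.56 ± 0.28, adjusted p = 0.0316). The DEAD-box RNA helicase RH12 (AT3G61240) was lower, at 10.6 ± 2.75 against 54.4 ± 4.87 CPM (-2.39 ± 0.25, adjusted p = 0.00013), and so was UBC11 (AT3G08690), a ubiquitin-conjugating enzyme, at 11.98 ± 1.59 against 25.8 ± 1.99 CPM (-1.12 ± 0.16, adjusted p = 0.0063). Altogether 16 of 18774 genes were called, 13 higher and 3 lower. At an unadjusted p under 0.05 there were 687, where 938.7 are predicted with no effect.

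HEI10 (AT1G53490), a RING protein of meiotic crossover formation, was higher at 10.3 ± 1.01 against 1.09 ± 0.504 CPM (3.24 ± 0.53, adjusted p = 0.0182). So were the calmodulin-like TCH3 (1.76 ± 0.28), AT2G21820 (1.74 ± 0.27) and AT4G21020 (1.64 ± 0.30). The chromatin reader SHL1 was lower (-1.23 ± 0.22). HSP17.4A was called higher (1.77 ± 0.29, 3.82 ± 1.09 against 1.32 ± 0.670 CPM). The other calls were LEA18 (1.16 ± 0.21), a late embryogenesis abundant protein, the dehydrin RAB18 (1.33 ± 0.23), AT1G03106 (1.44 ± 0.25), the auxin-conjugating BRU6 (1.27 ± 0.24), the zinc-finger protein PMZ (1.54 ± 0.29), and UBC12 (AT3G08700), the neighbour of UBC11, which had 0 reads in WT and 15 reads in the libraries labelled pif4, at least 7.97-fold higher.

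All 9 tested members of the seed storage list, which stands for embryo and ungerminated seed, had positive values (median 2.01, camera adjusted p = 2.39e-19, and 0.0811 with an estimated correlation). Of these, OLEO5 alone was called over all genes, and 8 were called when adjusted over the list alone. The globulin CRA1 (AT5G44120) stood at 331 ± 60.6 against 82.6 ± 72.5 CPM (1.98 ± 0.63, adjusted p = 0.809), CRU3 at 214 ± 47.2 against 42.6 ± 38.7 CPM (2.28 ± 0.71, adjusted p = 0.772) and CRU2 at 18.1 ± 0.753 against 1.95 ± 1.74 CPM (2.93 ± 0.72, adjusted p = 0.281). Without WT library b CRA1 lay at 2.98 and CRU3 at 3.304. Over the 6 libraries left out in turn they lay at 1.61 to 2.98 and 1.90 to 3.304, none called. Without the 4 libraries lettered a all 9 stayed positive (median 1.56) and none was called. The small heat shock protein list had a median of 0.16 with 1 member called, or 6 adjusted over the list alone. Its camera adjusted p was 0.0291, but 0.662 with an estimated correlation and 0.0617 with the column letter as a term. The oxidative stress list had a median of 0.30 (adjusted p = 0.0130, and 0.519 with an estimated correlation) with none called, or 2 higher adjusted over the list alone. Its members of highest mean over all 12 libraries were CAT2 (0.21 ± 0.14) and GOLS1 (0.68 ± 0.19). At 22 °C GOLS1 stood at only 10.2 CPM in the libraries labelled pif4 against 6.48 CPM in WT. Auxin genes had a median of -0.21 (adjusted p = 0.00402, and 0.219 with an estimated correlation), with IAA2 at -0.20 ± 0.14 and IAA19 at -0.22 ± 0.29. Brassinosteroid, gibberellin and elongation genes had a median of -0.17 (adjusted p = 0.0273, and 0.656 with an estimated correlation), with XTH15 at 0.11 ± 0.14 and XTH4 at -0.31 ± 0.19. The other 13 lists were not past the threshold. In 5 of them the median, the mean and the test differ in sign: PIF and light signalling (median -0.04, mean 0.06), chlorophyll (0.01 and 0.00), abscisic acid (-0.08 and 0.26), the clock (0.08 and 0.01, test down) and root (-0.02 and 0.01).

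These calls depended on single libraries. Without WT library a at 22 °C, UBC11, HSP17.4A and RH12 remained and made up the 3 calls, without WT library c there were 5, without WT library b 9, and without pif4 libraries a, b and c 7, 8 and 40. RH12 and UBC11 kept their call whichever library was left out (adjusted p up to 0.00548 and 0.0357), while the others did not. UBC11 lost it with only these groups in the fit (0.0712). OLEO5 lost its call without WT a (0.107), WT c (0.105) or pif4 a (0.0693), and AT2G21820 without WT a (0.0503) or WT c (0.0563). Leaving out any library but pif4 c ended the calls of HEI10 (0.0563 to 0.136), EM1 (0.0740 to 0.168), AT4G21020 (0.0852 to 0.206), BRU6 (0.0852 to 0.365) and PMZ (0.0852 to 0.363). TCH3 ended without any WT library or pif4 b (0.0517 to 0.136), SHL1 without WT a or c or pif4 b or c (0.0806 to 0.191), HSP17.4A without WT b or c or pif4 b (0.110 to 0.190), LEA18 without WT a or b or pif4 a (0.0930 to 0.231), and RAB18 without the same 3 (0.0932 to 0.198) and with the column letter as a term (0.1175). UBC12 ended without all but pif4 a (0.0700 to 0.184) and AT1G03106 without all but WT b (0.0554 to 0.184). With only these groups in the fit the calls of TCH3, AT2G21820, AT4G21020, HSP17.4A, LEA18, RAB18, BRU6 and PMZ ended as well (0.0712 to 0.420) and UBC12 was not tested. Total counts as library size ended those of AT4G21020, EM1, SHL1, UBC12, LEA18, RAB18, BRU6 and PMZ (0.0511 to 0.0651).

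**Figure D2:**
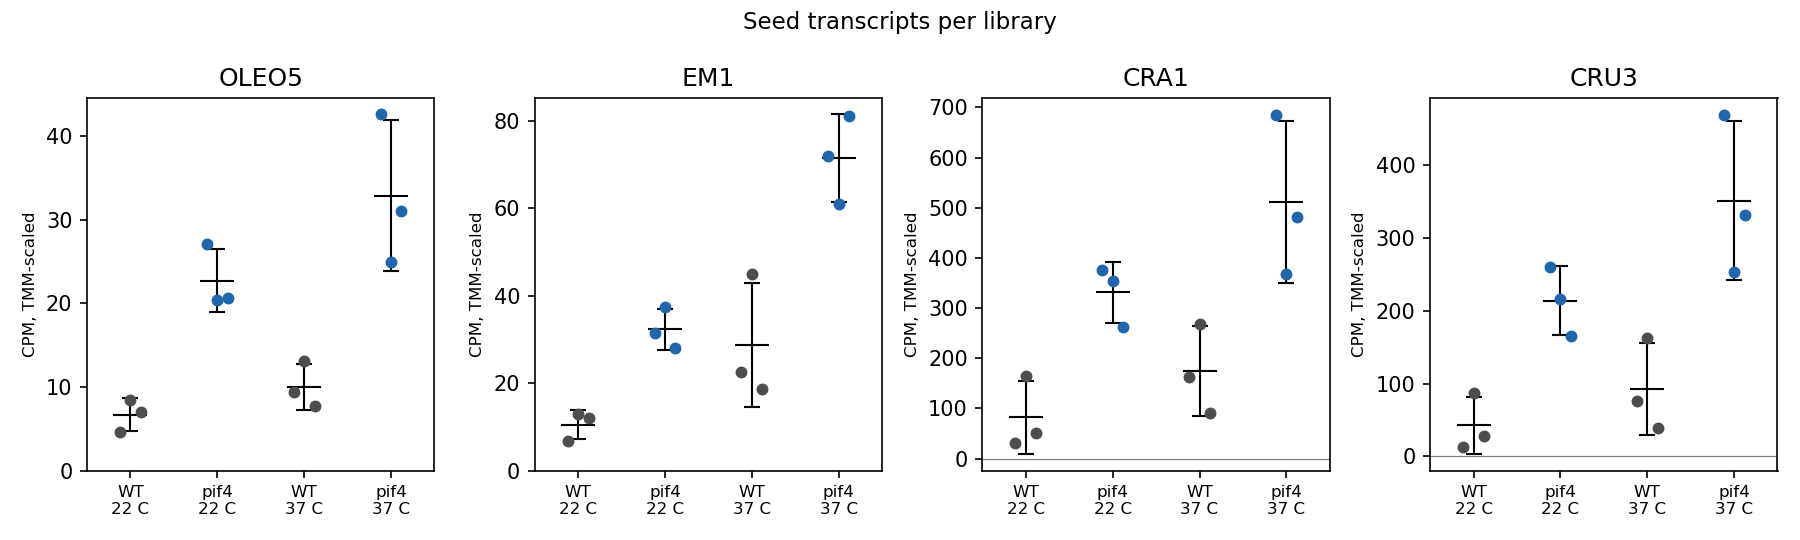
Points are the TMM-scaled CPM of OLEO5, EM1, CRA1 and CRU3 in each of 12 libraries (vertical axes), by genotype label and temperature (horizontal axis), and bars are mean ± SD of 3. At 22 °C OLEO5 lies between 20.5 and 27.1 CPM in the libraries labelled pif4 and between 4.59 and 8.44 CPM in WT.

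At 37 °C, UBC12 was at 36.6 ± 7.56 CPM in the libraries labelled pif4 against 2.56 ± 0.0582 CPM in WT (3.83 ± 0.35, adjusted p = 4.14e-05), and UBC11 at 187 ± 9.49 against 359 ± 48.7 CPM (-0.94 ± 0.14, adjusted p = 0.00935). OLEO5 again stood higher, at 32.9 ± 9.00 against 10.04 ± 2.77 CPM (1.69 ± 0.29, adjusted p = 0.0308), as did the aminotransferase AGT3 (AT2G38400), at 101 ± 23.7 against 39.3 ± 6.98 CPM (1.35 ± 0.18, adjusted p = 0.00308). In all 10 genes were called, 7 higher and 3 lower, of which 8 changed at least 2-fold. An unadjusted p under 0.05 was found for 1988 genes, where 938.7 are predicted with no effect, and for 1038 with only these groups in the fit. AT5G19110 (2.86 ± 0.49), the oxophytodienoate reductase OPR1 (1.45 ± 0.27), LEA18 (1.09 ± 0.19) and AT2G32150 (0.77 ± 0.14) were the other genes called higher. NIP2 (AT2G17730) was lower (-1.21 ± 0.21), and AT5G38050 had 1 read against 49 in WT, a ratio with a counting interval of 10.8 to 2537. RH12 (-1.29 ± 0.26, adjusted p = 0.0816) and EM1 (1.29 ± 0.27, adjusted p = 0.0869) were not called at this temperature. Both were without WT library b (adjusted p = 0.0393 and 0.0147), under DESeq2 (0.00262 and 0.00858), with no filter on low counts (0.0116 and 0.0231) and with the column letter as a term (0.0309 and 0.0257).

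All 9 seed storage genes again had positive values (median 1.69, camera adjusted p = 1.25e-12, and 0.106 with an estimated correlation), with OLEO5 called over all genes and 5 members adjusted over the list alone. CRA1 stood at 512 ± 161 against 174 ± 89.3 CPM, CRU3 at 351 ± 109 against 92.3 ± 63.3 CPM and CRU2 at 29.6 ± 10.96 against 5.47 ± 5.14 CPM, none of them called (adjusted p = 0.434, 0.397 and 0.242). As each library was left out their log2 values were 1.24 to 2.02, 1.54 to 2.65 (highest without WT b) and 1.97 to 3.34 (without WT c and WT a). Abscisic acid genes had a median of 0.26 (adjusted p = 0.000404, and 0.106 with an estimated correlation) with none called (3 adjusted over the list alone). The highest in mean level over all 12 libraries were ABI1 (0.10 ± 0.14) and RAB18 (1.01 ± 0.23, adjusted p = 0.105, but 0.0154 under DESeq2 and 0.0364 with only these groups in the fit). Small heat shock proteins had a median of 0.14 (adjusted p = 0.00330, and 0.493 with an estimated correlation), with HSP18.2 at -0.06 ± 0.16 and HSP22.0 at 0.14 ± 0.16. Chaperones had a median of 0.16 (adjusted p = 0.00330, and 0.115 with an estimated correlation), with HSP70-4 at 0.12 ± 0.14 and HSP90.1 at 0.17 ± 0.17. Auxin genes had a median of -0.18 (adjusted p = 0.00355, and 0.115 with an estimated correlation), with IAA2 at 0.00 ± 0.14 and IAA19 at -0.34 ± 0.29. The other 13 lists were not past the threshold, and signs differ for brassinosteroid (median 0.01, mean -0.28, test down), the clock (0.19, -0.04, up) and root (-0.13, 0.11, down). With the column letter as a term photosynthesis (camera adjusted p = 0.0051) and PIF and light signalling (0.0304) were past it, against 0.742 and 0.115 with an estimated correlation.

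The genes called at both temperatures were OLEO5, LEA18 and UBC12, higher in the libraries labelled pif4 (0.00485 genes for independent lists), and UBC11, lower (0.000479). With total counts as library size only UBC11 was left of these 4, as OLEO5 (adjusted p = 0.0517) and LEA18 (0.0742) were not called at 37 °C nor LEA18 and UBC12 (0.0543 each) at 22 °C. With RLE size factors LEA18 at 37 °C (0.0505) and with only these groups OLEO5 at 37 °C (0.0574), LEA18 at 22 °C (0.0975) and UBC11 at 22 °C (0.0712) were not called. Across genes the differences at 22 and 37 °C correlated with r = 0.228 (Spearman 0.0935), from separate libraries. UBC11 and UBC12 are similar neighbouring genes, so the split of reads between them is uncertain. Leaving out 1 library at 37 °C gave 6, 18 and 7 calls without WT a, b and c and 18, 4 and 2 without pif4 a, b and c. The 2 left without pif4 library c were AGT3 and UBC12, which kept their call whichever library was left out (adjusted p up to 0.0292 and 0.00172). The call of UBC11 ended without pif4 library b (0.0577) or c (0.0753), and that of LEA18 without any of the 6 (0.0534 to 0.138). OLEO5 ended without WT a or c or pif4 a or c (0.0710 to 0.128), NIP2 without all but WT b (0.0540 to 0.136), AT5G38050 without WT c or pif4 b or c (0.0887 to 0.138). Leaving out any library but pif4 a ended AT5G19110 (0.0515 to 0.136), OPR1 (0.0618 to 0.144) and AT2G32150 (0.0743 to 0.181). The call of OPR1 also ended with RLE (0.0636), total counts (0.0744) and only these groups (0.425). AT2G32150 ended with RLE (0.0654) and only these groups (0.0990), and AT5G19110 with only these groups (0.110).

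**Figure D3:**
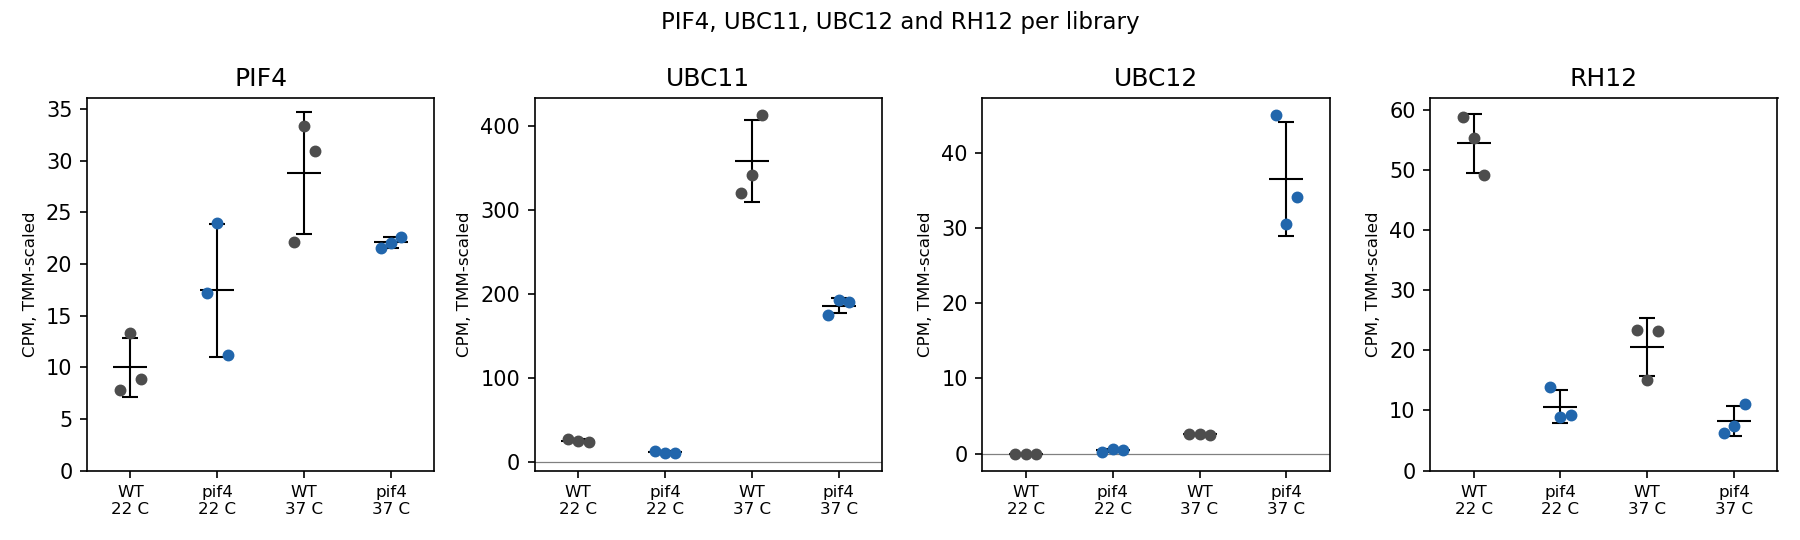
Points are the TMM-scaled CPM of PIF4, UBC11, UBC12 and RH12 in each of 12 libraries (vertical axes), by genotype label and temperature (horizontal axis), and bars are mean ± SD of 3. UBC12 lies between 30.6 and 45.1 CPM in the libraries labelled pif4 at 37 °C and between 2.50 and 2.62 CPM in WT, while PIF4 is read in all 12.

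No gene was called for a difference between the heat effects of the libraries labelled pif4 and of WT. The smallest adjusted p was 0.468 under edgeR, for BRU6, whose rise with heat was smaller in the libraries labelled pif4 (15.1 ± 5.38 to 43.7 ± 3.88 CPM) than in WT (6.11 ± 0.433 to 61.1 ± 5.11 CPM), a difference of -1.75 ± 0.32. HSP17.4A followed with -1.63 ± 0.34 (adjusted p = 0.524), and PIF4 lay at -1.16 ± 0.39 (adjusted p = 0.767). At an unadjusted p under 0.05 there were 1025 genes, where 938.7 are predicted with no effect. DESeq2 called 2 genes, BRU6 (adjusted p = 0.0116) and HSP17.4A (0.0145), as did edgeR without the filter on low counts (0.0225 for both), and without pif4 library c at 22 °C BRU6 was called (0.0218). No list was past the threshold. Photosynthesis had the smallest adjusted p, 0.0726 (median -0.24), which was 0.00301 with the column letter as a term and 0.964 with an estimated correlation. Adjusted over the list alone, 5 of 15 small heat shock proteins were lower and 0 higher (list median -0.05, camera adjusted p = 0.0991). Likewise, 2 of 21 heat shock factors were higher and 0 lower (highest value 2.12), and 1 of 13 oxidative stress genes was lower and 0 higher. None of these members was called over all genes. In simulated data without the heat response, 2-fold differences of this kind were recovered for 14.1% of seeded genes, all with a mean of at least 5 CPM. Smaller ones were mostly missed there, so the lack of calls does not exclude such differences.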

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

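The families tested for a difference between the heat effects of the libraries labelled pif4 and WT were defined after the table was opened. PIF4 was not called for this difference, at -1.16 on the log2 scale (unadjusted p = 0.00743, adjusted p = 0.767 over all genes). Past the threshold with the preset correlation, but not with an estimated one, were 3 families. Ribosomal proteins lay lower (median -0.19), with a camera adjusted p of 1.16e-07, and 0.717 with an estimated correlation. Proteasome subunits also lay lower (median -0.12, camera adjusted p = 0.0211, and 0.541 with an estimated correlation). Aquaporins lay higher (median 0.21, camera adjusted p = 0.0199, and 0.717 with an estimated correlation). No member of these families was called for this difference.

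The tests of temperature and of the column letters for the late embryogenesis genes were chosen only after the result or the data were seen. The test of seed tissue is recorded as written before. Its bound still rests on the pattern's genes, which were picked from calls in the same libraries, so its outcome is not independent support. The pattern is 6 genes picked from those called higher in the libraries labelled pif4 at 22 °C, not a fixed list (OLEO5, EM1, RAB18, LEA18, AT2G21820 and AT4G21020, median 1.60), of which OLEO5 and LEA18 were also called at 37 °C, while at 22 °C the seed storage list and the late embryogenesis family had an adjusted p of 0.0811 and 0.0574 with an estimated correlation. A larger share of ungerminated seed or embryo tissue is compatible with it, as the 8 other seed storage members had a median of 2.05 against a bound of 0.80. The SE set beside it, 0.68, is not that of the median. It belongs to the difference between the groups in the mean log2 CPM of these 8 genes, 2.45. The median less 2 of these standard errors, 0.68, lies below that bound. If the difference were confined to the libraries kept at 22 °C, the median of these 6 genes at 37 °C would lie within 2 standard errors of 0. It was 1.13, with an SE of 0.19 taken from their mean log2 CPM, which argues against this for the 6 genes as a set. Singly, only OLEO5 and LEA18 were called at 37 °C, and EM1 (adjusted p = 0.0869) and RAB18 (0.105) were not. With the column letter as a term 5 of 6 genes were called at 22 °C (not RAB18, adjusted p = 0.1175). This decides nothing, as each letter occurs once in every group. A difference of genotype, through slower germination or otherwise, stays open, as no measure of germination was available to test it.

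For the UBC11 and UBC12 pair the tests of shared reads and of the column letters were chosen only after the result or the data were seen. UBC11 was lower and UBC12 higher in the libraries labelled pif4. If reads had only moved between the paralogs and all were counted, their sum would be unchanged, but it differed by -0.69 (SE 0.11) at 37 °C and -1.05 (SE 0.11) at 22 °C. At 22 °C the sum is nearly UBC11 alone, as UBC12 had 0 reads in WT and 15 in the libraries labelled pif4. How reads that match both genes were counted is not known, so a loss of such reads is not excluded. With the column letter as a term 4 of 4 calls were made, which decides nothing, as each letter occurs once in every group. A difference in the sequence of this region between the lines was not tested.

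Both tests for PIF4 itself were chosen only after the result was seen. PIF4 reads were not lower in the libraries labelled pif4 at 22 °C, and at 37 °C the value was -0.40 (adjusted p = 0.681, not called). After a swap of all labels at 1 temperature the genes called at both would go in opposite directions, but 4 of 4 went the same way, which argues against it. These genes are few and not independent. UBC11 and UBC12 are neighbours, OLEO5 and LEA18 belong to the late embryogenesis pattern, and with total counts as library size only UBC11 was called at both temperatures. A swap of single libraries was not tested. A mutant transcript that is still counted could give the value of 0.76 at 22 °C (0.44 without pif4 library b), but counts hold no position along the gene, so this cannot be told from a wrong label at both temperatures.

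For other groupings of the libraries, the tests were written before the results were seen. With 3 against 3 libraries there are 10 splits, too few to judge: 1 of 10 reached the count for heat in WT (9672), heat in pif4 (9336), pif4 against WT at 22 °C (16) and at 37 °C (10), the real grouping itself, and the highest other count was 0 each time. For the difference between heat effects 40 of 40 drawn splits reached the real count of 0, as any count does, so this decides nothing, and the highest other was 1.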

How the results depend on the processing

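The count of genes that differ between the libraries labelled pif4 and WT was the least stable result, and the cause was not tested. At 22 °C the 16 calls became 86 with DESeq2, 52 with no filter on low counts, 8 with total counts as library size and 6 with only these groups in the fit, and 3 to 40 when each library was left out in turn. At 37 °C the 10 calls became 136 with DESeq2, 76 with no filter, 7 each with RLE, total counts and only these groups, and 2 to 18 when each library was left out. Chosen after seeing the data were the column letter as a term, with 27 calls at 22 °C and 55 at 37 °C, and a fit without the 4 libraries lettered a, with 2 (UBC11, RH12) and 3 (AGT3, UBC11, UBC12). The 0 calls for the difference between heat effects became 2 with DESeq2, 2 with no filter and 0 to 1 when each library was left out. Heat calls ran from 8270 to 9328 in WT and from 7920 to 8789 in pif4 when each library was left out. With total counts as library size PIF4 changed by 0.49 with heat in WT and -0.68 in the libraries labelled pif4, and NRT1.1 by -0.65. Near 0 at 37 °C, IAA2 turned to -0.0304 with DESeq2, -0.0284 with RLE, -0.0052 with total counts, -0.0280 with only these groups and -0.0734 without the libraries lettered a (-0.126 to 0.0898 when each library was left out), HSP18.2 to 0.0204 (-0.145 to 0.0204), and ABI1 to -0.0121 without the libraries lettered a. The brassinosteroid, gibberellin and elongation list turned direction for the difference between heat effects with the letter as a term (adjusted p = 0.973). With that term the reference genes were past the threshold for heat in WT (camera adjusted p = 0.0407) and in pif4 (0.0357). The named genes of the text kept direction and side of the threshold in 606 of 635 values for heat in WT, 248 of 260 in pif4, 234 of 324 at 22 °C, 226 of 298 at 37 °C and 31 of 36 for the difference. Over all genes of the naming rule it was 976 of 1038, 823 of 870, 448 of 533, 444 of 546 and 589 of 648. A gene that was not called counts as kept while it stays uncalled in the same direction, so these totals overstate how well calls held. The named genes of the text that lost their call gave 90 values at 22 °C and 52 at 37 °C, all from called genes.

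No paired analysis was possible because the columns carry letters that no label ties to replicate numbers, and the letter term is not a known pairing. The 10 comparisons with PIF4-L.1 and PIF4-L.2 and their alternatives were not run. A limma-trend analysis of the length-corrected columns, fixed before the data were examined, was run and its values were seen. Its heat results lay near those with total counts as library size, with mostly lower calls. It was then left out because 1 measure per library was kept, and its values, for heat or between the genotype labels, are not given here. A fit of only the groups compared is the full fit for the difference between heat effects. The lowest totals, 3176106 and 3234886 reads, limit what can be said of genes with few reads.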

Other observations

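Beyond the lists, class III peroxidases, which act on cell walls, fell most clearly with heat among 14 families: in WT 23 of 43 were lower and 1 higher (median -1.19, camera adjusted p = 0.000488, and 0.0245 with an estimated correlation), in pif4 22 lower and 2 higher (median -1.001, adjusted p = 0.000596, and 0.0249 with an estimated correlation). Histones were lower in 24 and higher in 3 of 39 cases in WT (median -1.28, adjusted p = 0.00247, and 0.494 with an estimated correlation). SAUR-like growth genes were lower in 24 and higher in 3 of 57 (median -1.20, adjusted p = 0.00740, and 0.309 with an estimated correlation), and expansins, which loosen cell walls, lower in 13 and higher in 4 of 24 (median -1.10, adjusted p = 0.0185, and 0.132 with an estimated correlation). Late embryogenesis abundant proteins were higher in 16 and lower in 3 of 28 (median 2.03, but 14 and 9 with a median of 1.01 with total counts as library size, adjusted p = 0.00124, and 0.195 with an estimated correlation), DnaJ proteins higher in 39 and lower in 17 of 106 (median 0.24, but -0.78 with total counts as library size, adjusted p = 0.0185, and 0.149 with an estimated correlation), and aquaporins higher in 15 and lower in 7 of 27 (median 0.75, but -0.27 with total counts as library size, adjusted p = 0.00740, and 0.309 with an estimated correlation). Not past the threshold were ribosomal proteins (90 higher and 29 lower of 349, but 17 and 246 with total counts as library size), proteasome subunits (12 and 3 of 35, but 5 and 25 with total counts), xyloglucan endotransglucosylases (6 and 8 of 22, 4 and 13 with total counts), cytochrome P450 enzymes (22 and 41 of 122, 9 and 76 with total counts), pentatricopeptide repeat proteins (24 and 37 of 197, 7 and 104 with total counts), aminoacyl-tRNA synthetases (11 and 12 of 51, 3 and 39 with total counts) and glutathione S-transferases (7 and 13 of 35, 3 and 20 with total counts).

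Between the genotype labels, late embryogenesis abundant proteins were higher in the libraries labelled pif4 in 2 of 28 cases at 22 °C (13 adjusted over the list alone, median 0.60, adjusted p = 3.86e-10, and 0.0574 with an estimated correlation) and in 1 at 37 °C (7 adjusted over the list alone with 1 lower, median 0.56, adjusted p = 4.07e-08, and 0.0558 with an estimated correlation). Glutathione S-transferases had a median of 0.28 at 22 °C (adjusted p = 9.57e-09, and 0.0843 with an estimated correlation) and 0.43 at 37 °C (adjusted p = 0.000319, and 0.283 with an estimated correlation), with none called over all genes. Ribosomal proteins lay at 0.06 at 22 °C (adjusted p = 0.00256, and 0.856 with an estimated correlation) and -0.14 at 37 °C (adjusted p = 0.000115, and 0.563 with an estimated correlation). Class III peroxidases lay at 0.01 at 22 °C (adjusted p = 0.0212, and 0.0843 with an estimated correlation) and 0.22 at 37 °C (adjusted p = 0.00514, and 0.0558 with an estimated correlation), SAUR-like genes at -0.13 at 22 °C (adjusted p = 0.0212, and 0.746 with an estimated correlation), and proteasome subunits at -0.13 at 37 °C (adjusted p = 0.00514, and 0.273 with an estimated correlation). With heat in pif4, the families past the threshold were the same 7 as in WT, with 6 of them losing the call with an estimated correlation (adjusted p = 0.0787 to 0.562).

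Deviations of the libraries lettered a from their group means correlated with each other by 0.0786 to 0.258 across genes. The 10 most abundant genes took 8.07 to 21.9% of reads per library. The genes next to UBC11 and UBC12, AT3G08680 and TH9, were not called at either temperature.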
